A study of Mus musculus with 12 samples.

How the data were processed

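The labels describe RNA of isolated cardiomyocytes from wild-type C57BL6 mice, purified with an RNeasy kit and prepared from 1.3 µg as polyA libraries with the VAHTS Universal V6 kit. Per the submitters' processing notes the reads went through fastp, HISAT2 and HTSeq against GRCm39; versions, annotation and strand setting are not given in the sources used here. The authors deposited gene counts and FPKM for 12 libraries, and each column was matched to a sample by the column name in its label. The deposited counts (22794 genes) were used for every test, and the deposited FPKM only as an alternative. Gene lengths implied by the counts and the FPKM were the same in all libraries over 12162 genes with at least 50 counts (largest relative difference 2.1e-08). Gene symbols were compared with reference tables of GRCm38.p6 and GENCODE vM21, where 22119 (97.0%) were found. Since that assembly is older than the one of the data, the tables served for names only and no positions are given.

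Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 14412. Counts were scaled with TMM and fitted with the edgeR quasi-likelihood model over all 12 libraries with the 4 groups as the only term. The 5 comparisons of a pair of groups and the interaction of nephrectomy and JV101 were each tested with a 2-sided F test, adjusted over all genes by Benjamini-Hochberg, with 0.05 as the threshold. Standard errors are on the log2 scale and were taken as the absolute log2 fold change divided by the square root of F. CPM are scaled with TMM and given as the mean ± SD of 3 libraries. Library measures were compared by exact permutation, 2-sided. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

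Gene lists numbering 49, of which 35 were pathways and 14 cell types, were fixed from general knowledge before the data were examined, with 1222 members, of which 29 are not in the table. The 47 with at least 5 measured members were tested with limma's camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list (median 0.422) and with limma's fry. Markers of liver (4 of 10 measured) and platelets (3 of 6) were not tested. A list's median is that of its measured members' log2 fold changes, and "adjusted over the list alone" means Benjamini-Hochberg over the members of that list only. How each such gene fared without 1 library was examined after the data were seen. A list's score in a library is the mean, over its measured members, of log2 CPM minus the gene's mean over the 12 libraries.

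Genes were named by a rule set in advance: the 8 passing genes with the largest change in each direction for the main 3 comparisons and 3 for the others, all 7 shelterin genes, up to 4 members of each list with the smallest p, and, where no gene passed, the 3 with the smallest p in each direction. Other genes named here were chosen after their values were seen, and results of some named genes are not reported here. The correlation between changes after nephrectomy and changes with JV101 was set against 100 simulations in which no gene changed and both comparisons used the same NX saline libraries.

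Alternatives were DESeq2, RLE and upper-quartile factors, no filter, a filter of 5 CPM in 3 libraries, fits of only the groups compared, the replicate number as a block, counts without mitochondrially encoded genes, limma on log2 FPKM with pseudocounts of 1 and 0.1, stricter thresholds (adjusted p 0.01, or a log2 fold change of 1) and leaving out each library. A pair of further fits with covariates, limma voom with sample weights and a fit without 3 libraries were added after the data were seen. In simulated counts resembling NX saline and sham saline (14412 genes, 200 of them changed), edgeR recovered 32% of 2-fold and 63% of 4-fold changes and called 4 unchanged genes. A list shifted by −0.5 in log2 was called with both the preset and an estimated correlation, and 0 of 44 lists sharing no gene with it were called with the preset. The simulated genes were drawn independently, without the correlation between genes of the real lists (median 0.422). The simulation therefore cannot show how often the preset calls unchanged lists in these data. Random groupings of the real libraries, given below, bear on this. For the interaction 83 of 100 groupings called 11 lists or more, as the real one did, and up to 29. Passing with the preset does not by itself set the real groups apart from random ones. A list said to rise or fall is described by the direction of its members in these libraries.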

Results

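RNA-seq of isolated mouse cardiomyocytes 16 weeks after surgery gave 12 libraries, 3 in each of 4 groups: sham surgery or 5/6 nephrectomy (NX), each with saline or with JV101, whose content the labels do not give. Each library held 26.4 to 33.8 M counts. Group means were 29.9 ± 2.85 M in sham saline, 29.7 ± 1.66 in sham JV101, 29.9 ± 3.22 in NX saline and 32.0 ± 1.65 in NX JV101 (mean ± SD, n = 3, as for all means here). The 13 protein genes of the mitochondrial genome took 36.7% to 69.0% of the counts of a library, with group means of 49.9 ± 16.9%, 48.6 ± 8.60%, 54.1 ± 11.1% and 44.1 ± 7.73% in the same order. The highest shares were 69.0% in sham saline replicate 2, 66.5% in NX saline replicate 3 and 58.4% in sham JV101 replicate 2, so the counts from nuclear genes ranged from 8.38 to 20.7 M. Between 16548 and 18342 genes were detected per library. No library measure differed between groups by an exact permutation test (smallest adjusted p = 0.933), which with 3 against 3 cannot go below 0.10. Libraries of different groups were as similar as libraries of the same group (r 0.913 to 0.980 and 0.913 to 0.974). The labels number the replicates and say nothing more about them, so the p-values measure only the spread between these samples.

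**Figure D1:**
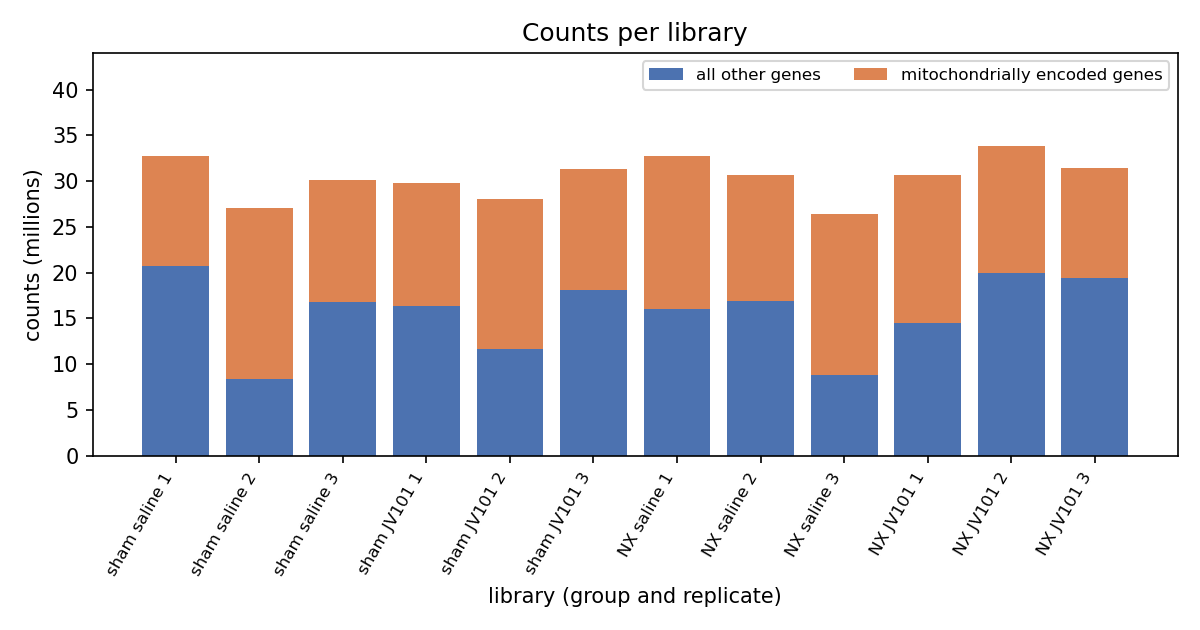
Counts in M (vertical axis) of each of the 12 libraries (horizontal axis, by group and replicate), each stacked bar 1 library with the mitochondrially encoded genes in orange and all other genes in blue. The mitochondrially encoded genes make up 69.0% of sham saline replicate 2 and 36.7% of sham saline replicate 1.

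After nephrectomy, in mice given saline, heat shock genes fell: all 18 measured members were negative, with a median log2 fold change of −0.61 (camera adjusted p = 1.75e-10, adjusted p = 0.827 with an estimated correlation). *Stip1*, an Hsp70-Hsp90 co-chaperone, averaged 105 ± 16.5 CPM in sham saline and 58.4 ± 4.27 in NX saline (log2 fold change −0.85, SE 0.21). *Hsp90ab1* went from 1165 ± 138 to 835 ± 95.7 CPM (−0.48, SE 0.16) and *Bag3* from 231 ± 20.5 to 151 ± 19.6 (−0.62, SE 0.20). Cell cycle genes rose, with 28 of 35 members positive and a median of 0.56 (camera adjusted p = 1.40e-05, 0.827 with an estimated correlation). Among them were *Cdk2* at 4.21 ± 0.411 and 7.94 ± 1.85 CPM (0.91, SE 0.25) and the mitotic kinesin *Kif11* (1.26, SE 0.45). Genes of branched-chain amino acid breakdown fell, 18 of 19 negative with a median of −0.25 (camera adjusted p = 3.35e-05, 0.984 with an estimated correlation), for instance *Bcat2* (−0.44, SE 0.17) and *Mmut* (−0.39, SE 0.19). Neutrophil markers rose by a median of 1.94, 7 of 8 positive (camera adjusted p = 0.000916, 0.827 with an estimated correlation), with *S100a8* at 0.803 ± 0.418 and 5.51 ± 2.87 CPM and *S100a9* at 1.09 ± 0.899 and 7.99 ± 4.96. Of these lists' members only *Stip1* passed adjusted over the list alone (edgeR, 0.0309). It did so in 1 of 6 fits that each left out 1 library (0.168 without sham saline replicate 2), and 12 of the 18 heat shock genes passed without sham saline replicate 1. Leaving out sham saline replicate 2 brought the heat shock median to −0.36. Without NX saline replicate 2 the cell cycle median was 0.28, and without NX saline replicate 3 the branched-chain median was −0.15.

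Matrix genes rose in the same comparison, with 36 of 39 members positive and a median of 0.50 (camera adjusted p = 3.35e-05, 0.984 with an estimated correlation). Without sham saline replicate 1 the median was 0.31 and the list no longer passed. *Col8a1* averaged 7.15 ± 2.32 CPM in sham saline and 15.9 ± 3.53 in NX saline (1.14, SE 0.50), and fibrillin, *Fbn1*, was at 1.03 (SE 0.49). Fibroblast markers were likewise positive, 17 of 17 with a median of 0.49 (camera adjusted p = 0.00492, 0.984 with an estimated correlation), and 0.30 and not passing without sham saline replicate 1. The scores of both lists ran together. In sham saline replicates 1 to 3 they were −0.70, −0.12 and −0.006 for matrix and −0.83, −0.20 and 0.031 for fibroblast. In NX saline replicates 1 to 3 they were −0.073, 0.27 and 0.43, and −0.21, 0.33 and 0.38. Whether more fibroblasts among the cells collected raised both lists was not tested. Genes of hypertrophy did not pass as a list: 18 were measured, with a median of 0.04. Within it *Nppb* was at −0.17 (SE 0.51), *Myh7* at 0.24 (SE 0.44), *Nppa* at −1.54 (SE 1.08) and skeletal actin *Acta1* at 1.03 (SE 0.41). The p53 targets (31 genes, median 0.03), senescence genes (25, 0.20) and DNA damage response genes (27, 0.01) did not pass either, with *Cdkn1a* at −0.10 (SE 0.68). The smallest p-values of single genes were those of *Niban3* (−2.26, SE 0.42; 1.52 ± 0.124 and 0.305 ± 0.126 CPM), the Wnt inhibitor *Sfrp5* (−2.43, SE 0.50; 1.15 ± 0.0460 and 0.209 ± 0.123) and *Gm42154* on the falling side, and of *LOC115486533*, *Iqck* and *Cdk2* on the rising side. *Gm42154*, *LOC115486533* and *Iqck* had 3 counts or fewer in a group, and *Iqck* had 0 in all sham saline libraries, so no fold is given for them.

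No single gene passed among 14412 tested in this comparison by edgeR (smallest adjusted p = 0.994), where 524 had an unadjusted p under 0.05, 236 up and 288 down. Such genes made up 3.6% here, 2.4% in NX JV101 against NX saline and 1.7% in sham JV101 against sham saline. The shares were 2.1% in NX JV101 against sham JV101, 6.2% in NX JV101 against sham saline and 1.8% in the interaction. If no gene changed, a fraction of 0.05 would be expected on average, which only NX JV101 against sham saline exceeded. The fraction varies widely where genes are correlated. Splits of the same libraries that mixed the groups gave up to 823 such genes for that comparison, against 895 in the real split. For NX JV101 against sham JV101 they gave up to 3787, against 299. The shares therefore do not show whether genes changed. DESeq2 called 1 gene, *Niban3* (adjusted p = 0.0272), and limma on the deposited FPKM and limma with voom weights called 0. Among genes at 10 CPM or more the median standard error was 0.188, so a 1.30-fold difference made 2 standard errors. Passing over 14412 genes takes a larger difference, and in the simulation 32% of 2-fold changes were recovered. Of 47 lists 14 passed with camera's preset correlation, 8 up and 6 down, 0 with an estimated correlation and 0 by the directional test of fry. Splits of the same libraries that mixed the groups called up to 24 lists with the preset. The 10 lists that did not pass in every fit without 1 library had medians of −0.24 to 1.75 (adjusted p of 0.984 or more with an estimated correlation), and 22 lists passed without NX saline replicate 1. *Nfil3* (−1.65, SE 0.40; adjusted over the list alone 0.0302), the immediate early gene *Nr4a3* (−1.63, SE 0.37; 0.0255) and *Dbh* (−1.66, SE 0.45; 0.0266) passed in their lists and kept that in 0, 2 and 1 of the 6 fits without 1 library (0.166 without NX saline replicate 2, 0.147 without NX saline replicate 1 and 0.134 without NX saline replicate 2).

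Markers of the mesothelium, the cell layer that covers the heart, were lower with JV101 after nephrectomy. All 10 measured markers were lower in NX JV101 than in NX saline, with a median log2 fold change of −1.20 that stayed between −1.49 and −1.02 whichever library was left out. As a list they had a camera adjusted p of 5.25e-20, and an adjusted p = 0.0889 with an estimated correlation, the smallest of any list in the 6 comparisons but not past 0.05. Adjusted over the list alone, 9 of the 10 passed, all of them lower, an adjustment that leaves the other lists and comparisons out of account. Adjusted over all genes, none of them passed by edgeR. *Lrrn4* averaged 11.9 ± 5.22 CPM in NX saline and 3.89 ± 0.868 in NX JV101 (−1.61, SE 0.32), *Muc16* 9.52 ± 2.84 and 3.06 ± 0.834 (−1.64, SE 0.32), *Krt19* 8.17 ± 3.25 and 2.66 ± 0.955 (−1.61, SE 0.34) and *Msln* 15.5 ± 4.85 and 6.81 ± 0.346 (−1.18, SE 0.25), each with a list-adjusted p of 0.00140. *Upk3b* followed at 28.8 ± 10.8 and 13.2 ± 1.32 CPM (−1.13, SE 0.25; 0.00151), then *Krt8* (−1.48; 0.0123), *Krt18* (−1.16; 0.0269), *Upk1b* (−1.22; 0.0269) and *Bnc1* (−0.95; 0.0368). *Krt19*, *Krt8*, *Lrrn4*, *Msln*, *Muc16* and *Upk3b* passed in all 6 fits without 1 library, and 6 of the 10 passed without NX saline replicate 3. None of the 10 is held by another list.

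**Figure D2:**
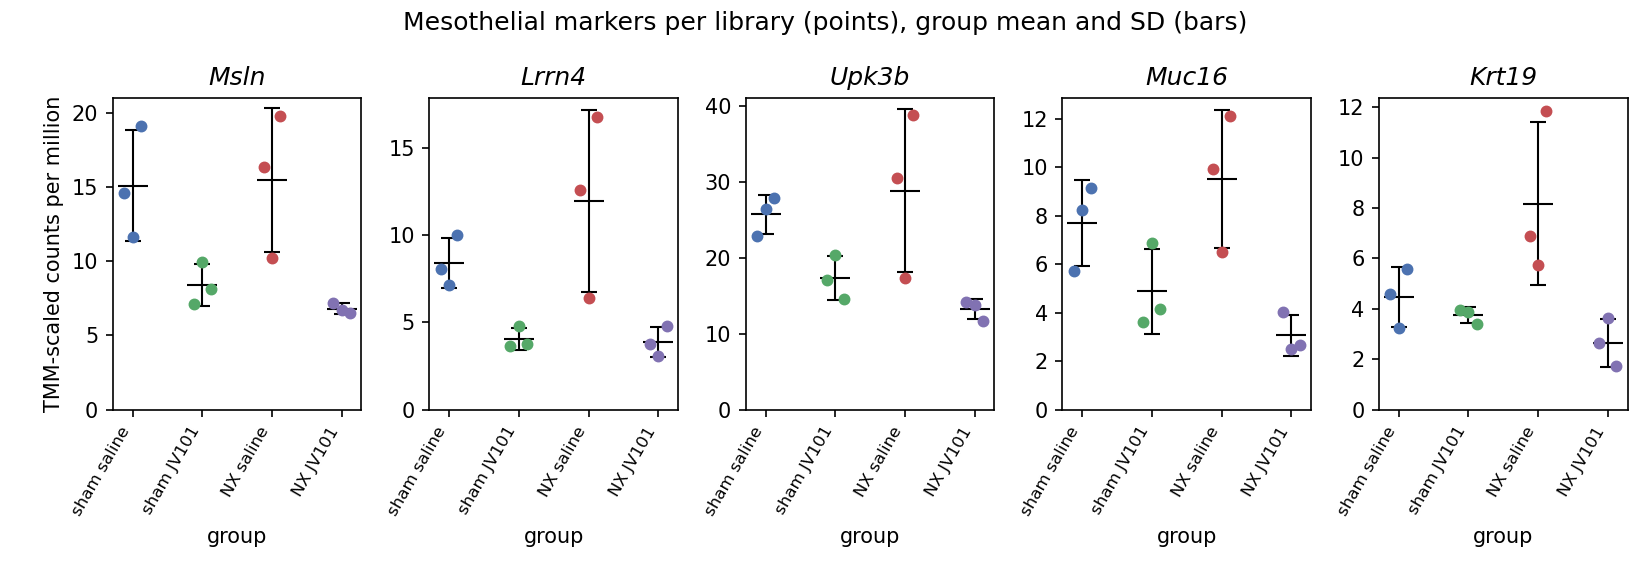
TMM-scaled CPM (vertical axis) of *Msln*, *Lrrn4*, *Upk3b*, *Muc16* and *Krt19* in the 4 groups (horizontal axis), each point 1 library, with bars for the group mean and SD. *Msln* averages 15.5 in NX saline and 6.81 in NX JV101.

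Fatty acid oxidation genes fell with JV101 after nephrectomy, 33 of 35 negative with a median of −0.23 (camera adjusted p = 3.75e-09, 0.986 with an estimated correlation). The largest members were *Pdk4*, which restrains pyruvate oxidation, at 955 ± 732 and 257 ± 79.6 CPM (−1.89, SE 0.66), the uncoupling protein *Ucp3* at 60.1 ± 32.8 and 19.6 ± 9.04 (−1.62, SE 0.55) and *Acot1* (−0.99, SE 0.34). The higher means of *Pdk4* and *Ucp3* came from NX saline replicates 2 and 3 (1102 and 1603, 66.5 and 89.3 CPM). In NX saline replicate 1 *Pdk4* was at 161, below the NX JV101 libraries (166 to 314), and *Ucp3* at 24.6, within them (9.66 to 27.3). None of the 35 passed adjusted over the list alone. The median was −0.37 without NX JV101 replicate 1 and −0.10 without NX JV101 replicate 2. Atrial cardiomyocyte markers rose, 12 of 12 positive with a median of 1.63 (1.40 to 1.78 without any 1 library; camera adjusted p = 0.000300, 0.986 with an estimated correlation). Atrial genes varied together from library to library, as given below, so the 12 are not separate results. The list's score was −0.22, −0.69 and −0.43 in NX saline replicates 1 to 3 and 1.06, 0.84 and 0.94 in NX JV101. Within sham saline alone it ranged from −2.27 to 1.49. Sarcolipin, *Sln*, averaged 9.81 ± 1.69 and 46.6 ± 20.1 CPM (2.25, SE 1.17), *Dkk3* 13.4 ± 1.41 and 40.3 ± 3.04 (1.59, SE 0.80), and *Nppa* 247 ± 97.0 and 735 ± 183 (1.57, SE 1.08). Lymphocyte markers fell by a median of −1.87, 9 of 11 negative (camera adjusted p = 1.06e-06, 0.652 with an estimated correlation). The median was −1.24 without NX JV101 replicate 3 and −0.93 without NX saline replicate 3. The B cell gene *Pax5* (−2.77, SE 0.84) passed adjusted over the list alone (0.0383), and in 1 of 6 fits without 1 library (0.175 without NX saline replicate 3). Neutrophil markers fell by −1.63, 7 of 8 negative (camera adjusted p = 0.000162, 0.652 with an estimated correlation), with *S100a8* at −2.99 (SE 1.01) and *Cxcr2* at −4.20 (SE 1.32), and by −0.80 without NX JV101 replicate 3 or −1.03 without NX saline replicate 1.

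Single genes again did not pass between NX JV101 and NX saline: edgeR called 0 (345 at unadjusted p under 0.05, 149 up and 196 down), as did limma on FPKM and with voom weights, and DESeq2 called 4, *Krt19*, *Lrrn4*, *Muc16* and *Spib* (smallest adjusted p = 0.0119). *Lrrn4*, *Muc16* and the lymphoid factor *Spib* (−4.55, SE 0.91; 0.956 ± 0.532 and 0.0384 ± 0.0349 CPM) had the smallest p-values of the falling genes, and *3110070M22Rik* (3.06, SE 0.74), *Tmem106c* (0.71, SE 0.17) and *Lrrc75b* (2.13, SE 0.56) those of the rising genes. The hypertrophy list had a median of 0.00, with *Myh7* at −0.34 (SE 0.44), and the p53 targets 0.11, with *Cdkn1a* at 0.07 (SE 0.68). Lists passed in 11 of 47 cases, 4 up and 7 down. The 6 that did not pass in every fit without 1 library had medians from −1.30 to 0.44 (adjusted p of 0.986 or more with an estimated correlation). Among them were the mitochondrially encoded genes, at −0.66 and at −0.26 without NX saline replicate 3. Without that library 23 lists passed, and 20 without NX JV101 replicate 1.

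Shelterin genes, which encode the protein cap of telomeres, did not pass, singly or as a list, in any of the 6 comparisons. *Terf1* was at 0.21 (SE 0.46) in NX saline against sham saline, *Terf2* at 0.09 (SE 0.21), *Terf2ip* at −0.15 (SE 0.12), *Tinf2* at 0.07 (SE 0.16), *Acd* at 0.02 (SE 0.21), *Pot1a* at 0.07 (SE 0.22) and *Pot1b* at −0.24 (SE 0.51; −0.72 without NX saline replicate 3 and 0.34 without sham saline replicate 2). In NX JV101 against NX saline the values in the same order were 0.24, −0.00, 0.20, 0.23, −0.01, 0.01 and 0.06, and in sham JV101 against sham saline 0.21, −0.07, −0.03, 0.12, 0.18, −0.21 and −0.32. NX JV101 against sham JV101 gave 0.24, 0.15, 0.09, 0.18, −0.17, 0.29 and 0.15, and NX JV101 against sham saline 0.45, 0.09, 0.06, 0.30, 0.01, 0.08 and −0.17. In the interaction *Terf1* to *Pot1b* were at 0.03, 0.06, 0.23, 0.11, −0.19, 0.22 and 0.38. The genes averaged 2.43 to 10.7 CPM, and the largest difference relative to its error, *Tinf2* in NX JV101 against sham saline (0.30, SE 0.16), had an unadjusted edgeR p of 0.0867. *Tert* had 0 to 6 counts per library and was not tested. Genes of telomerase and telomere replication passed only in sham JV101 against sham saline (median 0.16, 8 of 12 positive, camera adjusted p = 0.0270, 0.593 with an estimated correlation), with *Stn1* at 0.46 (SE 0.22). That list did not pass without sham saline replicate 1, sham saline replicate 2 or sham JV101 replicate 3, and its median was 0.10 without sham JV101 replicate 2.

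Heat shock genes were lower with JV101 after sham surgery, 17 of 18 negative with a median of −0.50 (camera adjusted p = 5.63e-13, 0.593 with an estimated correlation). The same sham saline libraries serve as reference here and after nephrectomy, and without sham saline replicate 2 the median was −0.39. The small heat shock protein gene *Hspb1* averaged 306 ± 138 CPM in sham saline and 157 ± 43.3 in sham JV101 (−0.97, SE 0.32), *Hsph1* 96.9 ± 42.7 and 45.6 ± 16.1 (−1.09, SE 0.37) and *Stip1* 105 ± 16.5 and 69.4 ± 14.7 (−0.60, SE 0.21). None of the 18 passed adjusted over the list alone. Mesothelial markers were also lower with JV101 after sham surgery, 9 of 10 negative with a median of −0.62 (camera adjusted p = 5.36e-06, 0.621 with an estimated correlation) and between −0.74 and −0.45 without any 1 library. In NX JV101 against NX saline their median was −1.20. *Msln* at 15.1 ± 3.77 and 8.40 ± 1.42 CPM (−0.85, SE 0.25) and *Lrrn4* at 8.40 ± 1.45 and 4.06 ± 0.637 (−1.06, SE 0.31) passed adjusted over the list alone (0.0297 each). Neither did without sham saline replicate 1 or 3 or without sham JV101 replicate 1 or 3 (highest 0.154). By edgeR 0 genes passed (245 at unadjusted p under 0.05, 105 up and 140 down), and DESeq2 and limma called 0. The smallest p-values were those of *Slc35e4* (0.96, SE 0.25), *Slfn4* (4.29, SE 1.18) and *Acta1* (1.30, SE 0.42; 109 ± 29.9 and 269 ± 18.7 CPM) among higher genes, and *Ckmt1* (−2.02, SE 0.52), *Zkscan3* (−0.53, SE 0.14) and *Xpnpep2* (−1.54, SE 0.42) among lower ones. Lists passed in 14 of 47 cases (3 up, 11 down). Of these, 12 did not pass in every fit without 1 library (medians −0.81 to 1.85, adjusted p of 0.593 or more with an estimated correlation), while 24 passed without sham JV101 replicate 1 and 22 without sham JV101 replicate 3.

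Among mice given JV101, interferon-stimulated genes were higher after nephrectomy, 47 of 48 positive with a median of 0.63 (camera adjusted p = 1.78e-10, 0.664 with an estimated correlation). The scores of this list overlapped, at 0.44, −0.45 and −0.86 in sham JV101 replicates 1 to 3 and −0.045, 0.47 and 0.99 in NX JV101 replicates 1 to 3. *Usp18* averaged 2.41 ± 0.682 CPM in sham JV101 and 6.12 ± 2.44 in NX JV101 (1.34, SE 0.56), and *Ifit1* 3.49 ± 0.696 and 14.3 ± 8.12 (2.03, SE 0.86). The median was 1.25 without sham JV101 replicate 1, 0.34 without sham JV101 replicate 3 and 0.35 without NX JV101 replicate 3. Cytosolic ribosomal protein genes rose by 0.21, 74 of 75 positive (camera adjusted p = 5.21e-15, 0.664 with an estimated correlation), for instance *Rpl3* (0.47, SE 0.23), and by 0.34 without sham JV101 replicate 1, 0.11 without sham JV101 replicate 3 and 0.14 without NX JV101 replicate 2. In the same comparison fibroblast (0.33), endothelial (0.36), macrophage (0.24) and smooth muscle (0.36) markers were higher and cardiomyocyte markers (−0.21) lower (camera adjusted p from 0.00110 to 0.0364, 0.664 or more with an estimated correlation). None of these passed in the same direction without sham JV101 replicate 3 (−0.11, −0.02, −0.18, −0.01 and −0.04) or NX JV101 replicate 2 (−0.10, 0.08, −0.30, 0.18 and −0.08), and the cardiomyocyte markers not without sham JV101 replicate 2 either. Without sham JV101 replicate 1 they were at 1.09, 0.97, 0.88, 0.78 and −0.32. Sham JV101 replicate 3 lay farthest out on the principal component that followed the fibroblast score (−82.0; r = 0.94 over 12 libraries). Mesothelial markers fell, 10 of 10 negative with a median of −0.34 (camera adjusted p = 0.00116, 0.664 with an estimated correlation; −0.53 without NX JV101 replicate 2), with *Muc16* at −0.67 (SE 0.32). Adipocyte markers were higher by 3.89, 7 of 8 positive (camera adjusted p = 5.36e-05, 0.664 with an estimated correlation), a median that stays at 3.89 with *Adipoq* and *Plin1*, which have 3 counts or fewer in a group, at their bound, and 2.13 without NX JV101 replicate 3. Within it *Cfd* (4.13, SE 1.29) passed adjusted over the list alone (0.0366), in 2 of 6 fits without 1 library (0.217 without NX JV101 replicate 3). Single genes called were 0 by edgeR (299 at unadjusted p under 0.05, 111 up and 188 down) and 0 by DESeq2 and limma. The smallest p-values were those of the cold-induced *Rbm3* (0.71, SE 0.18; 23.5 ± 1.23 and 38.4 ± 6.77 CPM), *Srp54b* (2.98, SE 0.84), *Npy1r* (1.44, SE 0.43), *Col11a2* (−1.53, SE 0.42), *Spib* (−3.37, SE 0.92) and *Aasdh* (−0.81, SE 0.22). Lists passed in 27 of 47 cases (15 up, 12 down), in 12 without sham JV101 replicate 3 and in 12 without NX JV101 replicate 2. The 23 that did not pass in every fit without 1 library had medians from −1.02 to 0.95, the p53 targets (0.24) and senescence genes (0.17) among them (adjusted p of 0.664 or more with an estimated correlation).

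NX JV101 against sham saline, the groups farthest apart in treatment, showed lower mesothelial markers, 9 of 10 negative with a median of −0.88 (camera adjusted p = 1.12e-08, 0.887 with an estimated correlation). *Msln* (−1.15, SE 0.25), *Muc16* (−1.33, SE 0.32), *Upk3b* (−0.96, SE 0.25) and *Lrrn4* (−1.11, SE 0.31) fell adjusted over the list alone (0.00668, 0.00740, 0.00783 and 0.0106) and passed in all 6 fits without 1 library. Heat shock genes fell, 18 of 18 negative with a median of −0.58 (camera adjusted p = 1.64e-09, 0.887 with an estimated correlation), 9 of them adjusted over the list alone. *Hspb1* was at −1.19 (SE 0.33), *Hsph1* at −1.30 (SE 0.37), *Stip1* at −0.74 (SE 0.21) and *Hsp90aa1* at −1.40 (SE 0.44), and 0 members passed without sham saline replicate 2 or 3 or NX JV101 replicate 1 or 3, against 12 without sham saline replicate 1. Fatty acid oxidation genes fell, 33 of 35 negative with a median of −0.44 (camera adjusted p = 1.34e-11, 0.887 with an estimated correlation), among them *Cpt2* at 161 ± 6.12 and 104 ± 19.2 CPM (−0.63, SE 0.19) and *Acot1* (−1.15, SE 0.34). Branched-chain amino acid genes fell by −0.31, 18 of 19 negative (camera adjusted p = 1.25e-05, 0.887 with an estimated correlation; −0.20 without NX JV101 replicate 2), with *Mccc2* at −0.62 (SE 0.20). Beside these, markers of other cells were higher, at 0.70 for fibroblast, 0.68 for endothelial and 0.77 for smooth muscle markers and 0.59 for matrix genes, and adult sarcomere genes were lower at −0.18 (camera adjusted p from 6.17e-05 to 0.0434, 0.887 with an estimated correlation). None of these lists passed without NX JV101 replicate 2, where they were at 0.35, 0.30, 0.53, 0.17 and −0.07. Other libraries whose absence ended a call were sham saline replicate 1 (fibroblast, matrix, sarcomere), replicate 2 (smooth muscle) and replicate 3 (endothelial, smooth muscle, sarcomere) and NX JV101 replicate 3 (smooth muscle).

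Unfolded protein response genes fell in that comparison by −0.23, 18 of 26 negative (camera adjusted p = 0.00148, 0.887 with an estimated correlation), with the chaperone *Hspa5* at 516 ± 114 and 317 ± 43.5 CPM (−0.70, SE 0.21). Their median was −0.49 without NX JV101 replicate 2, −0.55 without sham saline replicate 1 and −0.14 without sham saline replicate 2. Lymphocyte markers fell by −1.75, 9 of 11 negative (camera adjusted p = 5.18e-05, 0.887 with an estimated correlation), with *Ms4a1* at −3.08 (SE 1.01). They fell by −1.08 without NX JV101 replicate 1 and −0.52 without sham saline replicate 2. Adjusted over the list alone 4 of the 11 passed, and 0 to 2 without 1 library (0 without sham saline replicate 2 or NX JV101 replicate 2 or 3). edgeR called 0 genes (895 at unadjusted p under 0.05, 398 up and 497 down; smallest adjusted p = 0.780), limma 0, and DESeq2 3, *Gm26944*, *Gm32113* and *Zkscan3* (smallest adjusted p = 0.00916). *Zkscan3* averaged 29.9 ± 3.33 CPM in sham saline and 17.1 ± 1.71 in NX JV101 (−0.81, SE 0.14), *Gm32113* was at −1.34 (SE 0.25) and *Gm26944* at −2.16 (SE 0.41). The clock gene *Bhlhe40* averaged 30.0 ± 2.33 and 54.1 ± 6.30 CPM (0.85, SE 0.18), *Rbm3* was at 0.78 (SE 0.18) and *Sertad1* at 1.16 (SE 0.28). Lists passed in 20 of 47 cases (8 up, 12 down), in 10 without NX JV101 replicate 2, and the 14 that did not pass in every fit without 1 library had medians from −0.62 to 1.43 (adjusted p of 0.887 or more with an estimated correlation).

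Among the 11 lists that passed in the interaction with the preset correlation, neutrophil markers had the median farthest from 0, at −3.36. The interaction was negative for 8 of 8 of these genes (camera adjusted p = 1.58e-06, 0.577 with an estimated correlation). The median was −2.13 without sham JV101 replicate 1. *S100a8* averaged 0.803 ± 0.418 CPM in sham saline, 4.58 ± 4.70 in sham JV101, 5.51 ± 2.87 in NX saline and 0.694 ± 0.659 in NX JV101 (−5.46, SE 1.43). It passed adjusted over the list alone (0.0207), as did *Cxcr2* (−5.32, SE 1.68) and *S100a9* (−4.12, SE 1.39) at 0.0326 each, and 0 of them did so without sham saline replicate 2, sham JV101 replicate 1, NX saline replicate 1 or NX saline replicate 2. Heat shock genes had a positive interaction, 14 of 18 with a median of 0.40 (camera adjusted p = 1.65e-05, 0.772 with an estimated correlation; 0.18 without sham saline replicate 2). *Hspa1a* (4.34, SE 1.22) averaged 73.5 ± 55.2, 15.2 ± 13.3, 15.7 ± 11.8 and 65.3 ± 16.3 CPM in the same order of groups. Atrial markers were positive in 12 of 12 cases with a median of 2.54 (camera adjusted p = 5.45e-06, 0.772 with an estimated correlation; 1.68 without sham saline replicate 3), with *Sbk2* at 1.84 (SE 0.77). The atrial score ranged from −2.27 to 1.49 within sham saline and from −2.46 to 1.23 within sham JV101. Cell cycle genes were negative in 25 of 35 cases, median −0.51 (camera adjusted p = 1.45e-05, 0.756 with an estimated correlation; −0.29 without NX saline replicate 2 and −0.14 without sham JV101 replicate 1), with *Kif11* at −1.71 (SE 0.63). Mesothelial markers were negative in 10 of 10, median −0.55 (camera adjusted p = 7.22e-06, 0.756 with an estimated correlation; −0.89 without NX saline replicate 2 and −0.29 without NX saline replicate 3), with *Krt19* at −1.35 (SE 0.47).

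No single gene had an interaction by edgeR (256 at unadjusted p under 0.05, 152 positive and 104 negative), DESeq2 or limma. The median standard error at 10 CPM or more was 0.266, so that 2 standard errors made 1.45-fold, again less than passing over all genes takes. *Sfrp5* (2.76, SE 0.67), *Npy1r* (2.44, SE 0.61) and *Spats2l* (1.11, SE 0.29) had the smallest p-values above zero, and *S100a8*, *Spib* (−4.30, SE 1.17) and *Slfn4* (−5.50, SE 1.51) below it. Lists passed in 11 of 47 cases (7 positive, 4 negative), in 28 without sham JV101 replicate 1 and in 19 without NX saline replicate 3, and the 6 that did not pass in every fit without 1 library had medians from −0.41 to 0.71 (adjusted p of 0.772 or more with an estimated correlation).

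Changes after nephrectomy and changes with JV101 after nephrectomy, which share the NX saline libraries, had r = −0.38 over all genes. This was less negative than in simulated counts that held no change, where sharing those libraries gave a mean r of −0.51 (−0.55 to −0.48). The simulated genes were drawn independently, so that range leaves out the correlation between genes. Groupings of the real libraries at random, which keep it, gave a mean r of −0.47 (−0.74 to 0.079), a range that holds the observed value. With each NX saline library used in only 1 of these comparisons, r was between −0.05 and 0.30. Signs were opposite for 55.6% of genes, against 66.8% in the simulation, and the covariance was −0.0857 against −0.134 to −0.107. Over the random groupings these ranged from 39.8% to 86.5% and from −0.272 to 0.0203. The mesothelial list rose after nephrectomy by 0.36 (10 of 10 positive, camera adjusted p = 0.0451, 0.984 with an estimated correlation), but not without sham saline replicate 1 or 2 or NX saline replicate 1 or 3 (0.14 without the last).

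**Figure D3:**
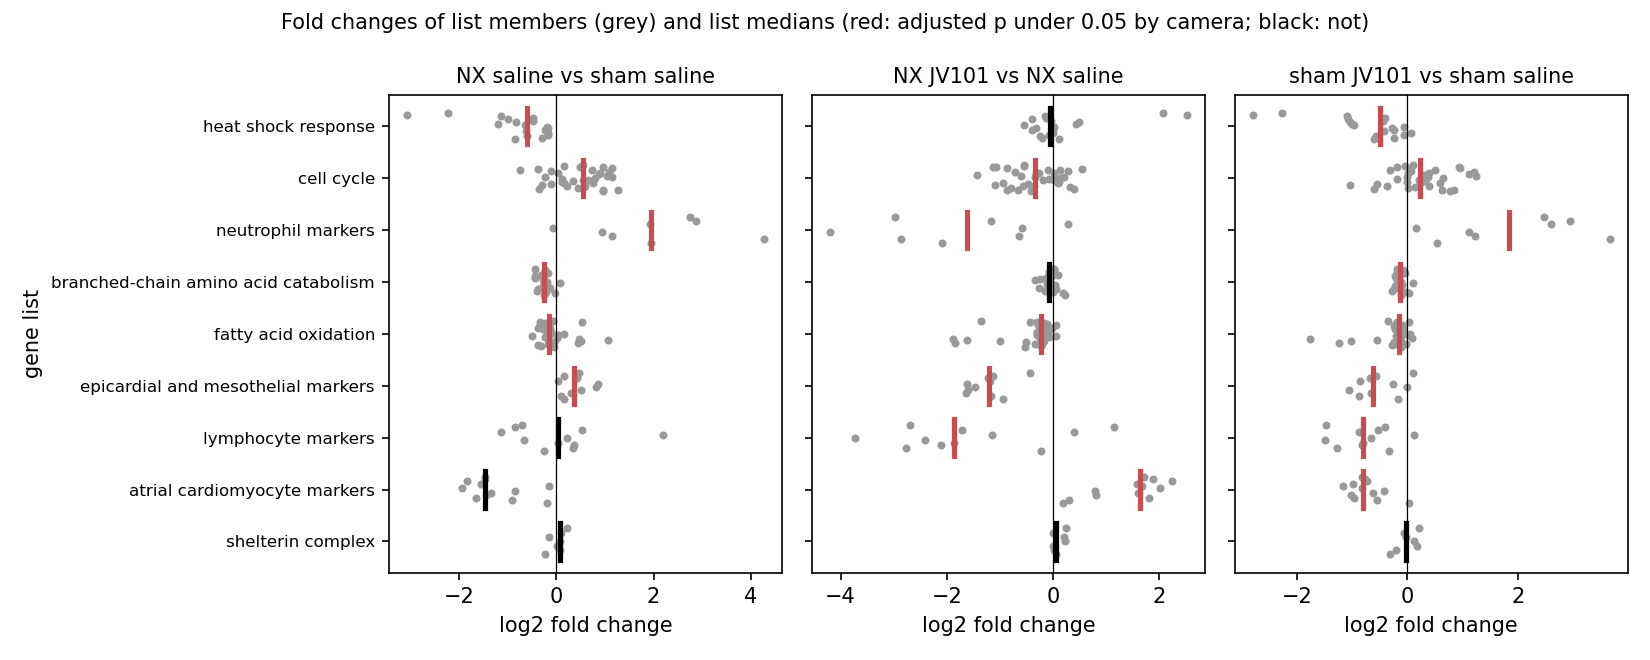
Log2 fold change (horizontal axis) of the members of 9 gene lists (vertical axis) in NX saline against sham saline, NX JV101 against NX saline and sham JV101 against sham saline, each grey point 1 gene and each bar a list median, red where camera's adjusted p was under 0.05 with the preset correlation. The mesothelial median is −1.20 in NX JV101 against NX saline and −0.62 in sham JV101 against sham saline.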

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

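The tests weighing mesothelial markers (other than the second list), heat shock genes and the absence of called genes, and the groupings for the correlation of changes, were chosen after the result was seen.

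The interaction of nephrectomy and JV101 passed in 11 lists by camera with the preset correlation, and in 0 with an estimated correlation (smallest adjusted p = 0.577). Medians were −3.36 for neutrophil markers, 2.54 for atrial markers, −0.55 for mesothelial markers, −0.51 for cell cycle genes and 0.40 for heat shock genes. Interferon-stimulated genes were at 0.71 (41 of 48 positive) and antigen presentation at 0.60 (20 of 20). Without sham saline replicate 1 these were 0.08 and 0.11 and did not pass, and neither passed without sham JV101 replicate 3. Their highest medians were 1.20 for interferon-stimulated genes, without sham JV101 replicate 1, and 1.31 for antigen presentation, without NX saline replicate 3. Immediate early genes were at 0.49 (22 of 27 positive; 0.20 and not passing without sham JV101 replicate 3). Cytosolic ribosomal proteins were at 0.14 (73 of 75 positive; 0.02 without sham JV101 replicate 3, and not passing without sham saline replicate 2 or 3 or NX JV101 replicate 2 either). Schwann and neuronal markers were at 0.71 (6 of 8 positive), did not pass without sham JV101 replicate 3, NX saline replicate 1 or 2 or NX JV101 replicate 2, and had a median of 0.24 without sham saline replicate 2 and 1.37 without NX saline replicate 3. Mitochondrially encoded genes were at −0.41 (12 of 13 negative), with −0.02 without sham JV101 replicate 2 and −1.15 without sham saline replicate 2, and did not pass without 6 of the 12 libraries taken singly.

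Grouping the libraries otherwise gave as many lists. For the interaction, 83 of 100 groupings called 11 lists or more (highest other 29). As many genes as the real grouping, which called 0, were called in 100 of 100, a count that any grouping reaches. The highest other was 302 genes, and its cause was not tested. The 10 splits of 6 libraries are too few for a share under 0.05. The lists called, with the highest other split, were 14 and 24 for NX saline against sham saline (9 splits called as many, the real one included), 11 and 27 for NX JV101 against NX saline (8), 14 and 27 for sham JV101 against sham saline (10), 27 and 30 for NX JV101 against sham JV101 (2), and 20 and 25 for NX JV101 against sham saline (5). Genes called by edgeR were 0 in each real split, which any split reaches, so that 10 of 10 splits called as many says nothing about the grouping, with a highest other of 5 in sham JV101 against sham saline and 0 elsewhere. The correlation of −0.38 between changes after nephrectomy and changes with JV101 was matched or passed downwards in 75 of 100 groupings (lowest other −0.74).

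Mesothelial markers lower with JV101 after nephrectomy, with a median of −1.20, were weighed against technical explanations. A smaller share of all cells other than cardiomyocytes is argued against: the mesothelial score minus the mean score of fibroblast, endothelial, macrophage and smooth muscle lists differed by −1.39 (pooled SD 0.532), while those other scores differed by 0.193. A single library is argued against too, since the median closest to 0 without 1 library was −1.02, without NX saline replicate 3. Fewer mesothelial cells among those collected may be the source: a second list of 14 mesothelial genes, sharing none with the other, was negative in 12 (85.7%; median −0.65), with *Podxl* at 172 CPM (0.37, SE 0.47), *Ezr* at 36.7 (−0.19, SE 0.20) and *Krt7* at 2.53 (−1.38, SE 0.42), and whether that came from cell collection or from an effect of JV101 on the heart's surface was not tested. Averaged over both surgeries the first list had a median of −0.94 with JV101, with camera adjusted p = 3.26e-20 at the preset and 0.0861 with an estimated correlation. Such an average can pass through 1 surgery alone, so the test cannot show an effect in both. An effect in both surgeries stays open.

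Heat shock genes lower after nephrectomy, with a median of −0.61, do not rest on 1 library alone: the median closest to 0 was −0.36, without sham saline replicate 2. The list's score was 0.88 and 0.73 in sham saline replicates 2 and 3. Sham saline replicate 1, at −0.16, lay within the scores of NX saline (−0.43, −0.24 and −0.018). Leaving out 1 library at a time cannot show how far the difference rests on sham saline replicates 2 and 3 together. A stress of cell isolation shared with immediate early genes cannot be told apart from an effect of nephrectomy, because over 12 libraries the scores of these lists correlated with r = 0.41 (permutation p = 0.184, rho 0.48 with p = 0.114; r = 0.43 with group means removed and 0.63 without the 2 farthest libraries). A biological effect of nephrectomy stays open, and sham saline was also above sham JV101 for these genes, by a median of −0.50 in sham JV101, a comparison that uses the same sham saline libraries.

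That edgeR called 0 genes was weighed against spread between libraries that hides changes. With the score of cells other than cardiomyocytes as a covariate, 0 genes passed in the 6 comparisons (806, 754, 525, 344, 1107 and 562 at unadjusted p under 0.05, in the order NX saline against sham saline, NX JV101 against NX saline, sham JV101 against sham saline, NX JV101 against sham JV101, NX JV101 against sham saline, interaction). With the difference of *Dbp* and *Arntl* as a covariate for clock phase, 0 passed as well (1073, 428, 387, 436, 1932 and 285). Without a covariate the counts were 524, 345, 245, 299, 895 and 256, and the median standard error of all genes was 0.269, 0.268, 0.268, 0.267, 0.268 and 0.379. It was 0.207, 0.202, 0.202, 0.211, 0.213 and 0.286 with the cell score, and 0.272, 0.263, 0.278, 0.259, 0.300 and 0.364 with the clock covariate, lower in 6 and in 3 of the 6 comparisons. These values do not decide whether either kind of spread is part of the cause, and changes too small to pass stay open.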

How the results depend on the processing

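The fits without 3 libraries of high mitochondrial share, those with covariates and voom with sample weights were chosen after the data were seen; the other settings were fixed before the data were examined. Where a value below moved, the cause was not tested. DESeq2 called 1 gene in NX saline against sham saline, 4 in NX JV101 against NX saline and 3 in NX JV101 against sham saline where edgeR called 0. With an estimated correlation, and by the directional test of fry, 0 lists passed in each of the 6 comparisons (fry's test for mixed directions called 1, in NX JV101 against NX saline). Of 1323 medians of lists that passed, 882 kept direction and call, 401 kept the direction without the call, and in 40 the sign of the median or the direction of camera's test turned. Of 9228 values of named genes, 8 newly passed, 26 changed sign by more than their error and 103 changed sign within it.

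On log2(FPKM + 1), *Acd* and *Terf2* in NX JV101 against NX saline were at 0.24 and 0.24, and on log2(FPKM + 0.1) at 0.32 and 0.34. FPKM lack TMM scaling, and the median of all genes there was 0.21 and 0.32, close to the values of both genes, against 0.00978 from counts. The median of all genes was 0.11 and 0.18 in NX JV101 against sham JV101 (0.00331 from counts), 0.18 and 0.29 in NX JV101 against sham saline (0.0276) and 0.14 and 0.21 in the interaction (−0.0261).

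Without the 3 libraries over 55% mitochondrial, 24 lists passed in NX JV101 against NX saline. Medians were 0.11 for mesothelial markers (NX saline against sham saline), 0.0219 for glucocorticoid-responsive genes (sham JV101 against sham saline), and for mitochondrially encoded genes 0.0308 in NX JV101 against sham JV101 (*ATP6* 0.28) and 0.14 in NX JV101 against sham saline (*COX2* 0.27, *ND2* 0.0454; *Pot1b* 0.37). With the non-cardiomyocyte score as a covariate 9 lists passed in NX saline against sham saline, 14 in NX JV101 against sham JV101 and 10 in NX JV101 against sham saline. In NX JV101 against sham JV101 the values were then 0.0306 for *Myocd*, −0.0732 for senescence genes, 0.00643 for adult sarcomere, 0.0370 for calcium handling, 0.0211 for branched-chain amino acid catabolism, 0.0621 for mitochondrial biogenesis, −0.0682 for matrix, 0.0286 for cardiomyocyte, −0.0462 for fibroblast, −0.157 for macrophage and −0.0183 for Schwann markers. In NX JV101 against sham saline they were −0.0884 for *Terf1*, −0.0108 for adult sarcomere and −0.0473 for endothelial markers. With clock phase as a covariate *Pot1b* was at 0.38 there. The correlation of −0.38 between changes after nephrectomy and with JV101 was 0.303, −0.0482 and 0.0254 with NX saline replicate 1, 2 or 3 used only in the JV101 comparison, and 0.137, 0.0748 and 0.13 with it used only in the nephrectomy comparison, where no library is shared.

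Leaving out 1 library at a time, lists passing ranged from 10 to 22 (NX saline against sham saline; 22 without NX saline replicate 1), 8 to 23 (NX JV101 against NX saline; 23 without NX saline replicate 3), 14 to 24 (sham JV101 against sham saline; 24 without sham JV101 replicate 1), 12 to 27 (NX JV101 against sham JV101; 12 without sham JV101 replicate 3 or NX JV101 replicate 2), 10 to 25 (NX JV101 against sham saline; 10 without NX JV101 replicate 2) and 10 to 28 (interaction; 28 without sham JV101 replicate 1). The correlation of changes ranged from −0.59 to −0.30.

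In NX saline against sham saline, ribosomal proteins ranged from −0.0271 to 0.193 and *Pot1b* from −0.72 to 0.34. In NX JV101 against NX saline, immediate early genes ranged from 0.0570 to 0.548. In the interaction *Tap1* ranged from −0.32 to 2.32. In sham JV101 against sham saline the ranges were −1.13 to 0.16 for antigen presentation, −1.98 to −0.11 for atrial markers, −0.310 to 0.0214 for branched-chain genes, −0.281 to 0.0189 for fatty acid oxidation, −0.495 to 0.0533 for immediate early genes, −0.92 to 0.18 for Schwann markers, −0.29 to 0.62 for *Cnp*, −1.26 to 5.28 for *Ngp*, −1.54 to 0.53 for *Nlrc5* and −0.67 to 0.25 for *Pot1b*.

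In NX JV101 against sham JV101 they were −0.485 to 0.00854 for calcium handling, −0.0224 to 0.965 for endothelial, −0.13 to 0.90 for matrix, −0.11 to 1.09 for fibroblast, −0.30 to 0.88 for macrophage, −0.325 to 0.0407 for mitochondrial biogenesis, −0.691 to 0.0287 for mitochondrially encoded, −1.66 to 0.15 for neutrophil, −0.0485 to 1.12 for Schwann, −0.0947 to 0.940 for senescence and −0.0102 to 0.776 for smooth muscle genes, −1.38 to 0.27 for *ATP6*, −4.61 to 2.67 for *Ngp* and −1.76 to 0.23 for *S100a9*. The fitted value of *Cd3g*, which has 3 counts or fewer in a group, ranged from −2.49 to 0.44. In NX JV101 against sham saline they were −0.96 to 0.16 for mitochondrially encoded genes, −1.35 to 0.28 for *COX2*, −0.999 to 0.0614 for *ND2*, −0.33 to 3.41 for *Pck1* and −0.41 to 0.40 for *Pot1b*.

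The replicate number as a block gave 0 genes in each comparison by edgeR (405, 263, 214, 219, 649 and 235 at unadjusted p under 0.05, in the order NX saline against sham saline, NX JV101 against NX saline, sham JV101 against sham saline, NX JV101 against sham JV101, NX JV101 against sham saline, interaction). Libraries with the same number were not alike: after removing group means, 6 of 18 such pairs correlated above 0.1 (−0.50 to 0.25), and 2 of 12 libraries correlated best with their own number. At unadjusted p under 0.05 limma on log2(FPKM + 1) had 193, 364, 87, 199, 709 and 167 genes and voom with sample weights 1430, 1496, 587, 2586, 2330 and 1150, with 0 passing in each.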

Other observations

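The tests of this part were chosen after the values were seen.

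The clock genes *Arntl* and *Dbp* separated the libraries, unevenly over the groups, while *Per1* and *Nr1d1* did not. *Arntl* was at 0.92 to 1.58 CPM and *Dbp* at 57.0 to 79.1 in sham JV101 replicate 3, NX saline replicate 2 and NX JV101 replicates 1 and 3 (none of them sham saline), against 5.47 to 14.8 and 6.999 to 36.7 in the other libraries. *Per1* was at 38.5 to 71.6 in the same libraries against 27.3 to 54.6 in the others, and *Nr1d1* at 21.6 to 42.0 against 16.9 to 48.8. *Pdk4* was at 1025 and 748 CPM in sham saline replicates 2 and 3 and at 1102 and 1603 in NX saline replicates 2 and 3, and between 161 and 314 elsewhere. The interferon-induced GTPases *Iigp1* and *Gbp6* were at 301 and 156 CPM in sham saline replicate 1 and at 279 and 133 in NX JV101 replicate 3, against 13.1 to 69.2 and 10.1 to 70.2 in the rest. *Hspa1a* was at 98.5 and 112 in sham saline replicates 2 and 3, at 54.2, 84.1 and 57.7 in NX JV101 replicates 1 to 3, and at 4.28 to 30.6 in the others. *Afp*, a gene of the fetal liver, was at 19.2 CPM in NX JV101 replicate 1 and 9.87 in sham saline replicate 2.

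Atrial genes varied together from library to library. *Nppa* ranged from 24.7 CPM in sham saline replicate 2 to 1332 in sham saline replicate 3, and *Myl7* from 3.93 to 240. Their log2 CPM correlated with r = 0.97 over 12 libraries (permutation p = 3.0e-05, adjusted 8.0e-05 over 4 correlations; rho 0.94), 0.96 with group means removed and 0.93 without the 2 farthest libraries. A share of atrial cells that differs between hearts may be the source, as a hypothesis.

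Airway genes appeared in 5 libraries. *Scgb1a1*, of airway club cells, was at 42.7 CPM in sham saline replicate 3, 19.98 in sham JV101 replicate 3, 108 in NX saline replicate 2, 80.1 in NX saline replicate 3 and 33.3 in NX JV101 replicate 1, and at 0 to 4.10 in the others. *Bpifa1* was at 184, 53.9, 205, 76.7 and 81.7 CPM in the same libraries and at 0.0249 to 2.89 in the others. Of 11 other airway genes listed, 8 had the same 5 highest libraries as *Scgb1a1*. Airway tissue carried along with some hearts may be the source, and the labels name no step that would have removed it other than the isolation of cardiomyocytes.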
